A study of Rattus norvegicus with 12 samples.

How the data were processed

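Total RNA in 12 samples of thoracic aorta from male rats was labelled with Cy3 and hybridised to single-colour Agilent arrays. The samples fell into the groups WKY, SHR-C, SHR-Bh and SHR-Ca by their titles, 3 in each. The labels also name a low-dose BSJY group, which is not analysed here. Rats were 12 weeks old at the start and were treated for 16 weeks, while the sample labels give an age of 32 weeks. The sources used here do not resolve that difference.

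The authors deposited 1 scanner output per array with the intensity of each spot. Per the file headers, Agilent Feature Extraction 11.0.1.1 subtracted the background and removed spatial trends within each array to give the processed intensity. No step between arrays is recorded there. The flags for spots well above background, for saturation and for outliers come from the same software. Each array had 43040 spots, of which 41623 were not controls. No spot of those was saturated on any array.

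Spots marked as outliers were left out, log2 of the processed intensity was averaged over the spots of a probe, and each array's 75th percentile was subtracted. That percentile was an intensity of 182.0 to 384.8 on the WKY arrays and 109.8 to 190.2 on the SHR arrays. The median of 38321 probes was 41.1 to 82.6 on WKY and 12.7 to 26.3 on SHR arrays, so the same log2 level stands on a dimmer signal in SHR. A probe was tested if it was well above background on all 3 arrays of at least 1 group, which kept 29618 probes (77.3%). Where a probe was not well above background on any array of a group, the fold is a bound: the mean of the brighter group against the mean, per array of the dimmer group, of the higher of the probe's own level and the lowest level among probes well above background.

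Of 62 probes with an accession, 39 matched 38 genes in the reference table of rat genes, and 23 did not match. The build named in the array design differs from that of the table, so no coordinates are given. A gene with more than 1 probe was represented by the brightest. The 10 to 30 spots of a named gene on 1 array had a median SD of 0.062 on the log2 scale where the probe was well above background. The median SD between arrays of a group was 0.23 to 0.40 over all tested probes. Most of those have 1 spot, so the values cover unlike probes.

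All 4 groups were fitted together in limma 3.58.1 under R 4.3.3 with 1 mean per group, and moderated two-sided tests were adjusted by the Benjamini-Hochberg method over all probes tested, with a threshold of 0.05. The contrasts were SHR-C against WKY, each treatment against SHR-C, and SHR-Bh against SHR-Ca. Counts across contrasts that share arrays were set beside independent lists and beside 100 simulations of unchanged groups with the same residual covariance. The fit was checked on simulated arrays with 29514 probes, of which 100 were changed 2-fold and 100 were changed 4-fold per contrast. It recovered 7 and 52 of these for SHR-C against WKY, 4 and 45 for SHR-Bh against SHR-C, 3 and 46 for SHR-Ca against SHR-C, and 0 and 51 for SHR-Bh against SHR-Ca, with 1 to 4 false calls. The simulated noise was independent, with 1 SD per probe pooled over the 4 groups, and held no arrays lying apart. So few probes were changed that the recovery does not carry over to SHR-C against WKY, where most probes passed.

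Named genes were chosen by a rule written before the data were examined, as were the tests of the comparisons and most other settings. The rule took up to 10 genes with the largest rise and 10 with the largest fall among those past the threshold with no overlap between groups and well above background on all arrays of 1 group. Where none passed, it took the 5 with the smallest p. It also took members of gene lists that pass their test, 16 genes of blood pressure control, the vessel wall, fat and the clock whatever their p, and up to 5 genes that moved back towards WKY. None of those 16 genes was named on the array, and 2 of the 648 genes on the 27 lists of pathways and cell types were, at most 1 per list. A list test needed 5 genes, so none of the 4 planned list tests could be run and no cell type could be scored. Unnamed probes are given by ID, 2 per direction and contrast.

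A shared scan time in the headers put the arrays into 5 sessions. Session 1 held WKY 1 to 3, session 2 SHR-C 1, session 3 SHR-C 2, SHR-C 3, SHR-Ca 1 and SHR-Ca 2, session 4 SHR-Bh 1, SHR-Bh 3 and SHR-Ca 3, and session 5 SHR-Bh 2. The session stood for the slide. It entered as a fixed block among the 9 SHR arrays for the treatment contrasts, which left 3 residual degrees of freedom, and as a random block (consensus correlation 0.11) for contrasts with WKY. Other alternatives were quantile normalization, normexp background correction with an offset of 50, no filter and a strict filter on dim probes, outlier spots kept, an intensity trend with robust variance, array weights, only the compared groups in the fit, the replicate number as a block, the mean of the probes of a gene, and leaving out each array in turn. Normexp was planned on the mean spot intensity and was run on the median spot intensity and the median local background, the pair used here. Its offset lies above the median intensity of every SHR array (12.7 to 26.3), so it shrinks the log2 changes of dim probes by construction. The labels do not say what a replicate number marks. By the criterion that the deviations from the group means of all same-numbered arrays correlate above 0.1, the numbers paired the arrays of SHR-C and WKY (r of 0.477, 0.176 and 0.227 for numbers 1, 2 and 3) and not those of the other 3 comparisons. Figures were drawn with matplotlib 3.10.9.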

Results

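RNA from the thoracic aorta of male rats was measured on 12 single-colour Agilent arrays. The rats were Wistar-Kyoto (WKY), the normotensive strain commonly set beside the spontaneously hypertensive rat (SHR), and SHRs in 3 groups: untreated (SHR-C), given a high dose of BSJY (SHR-Bh), and given captopril (SHR-Ca). BSJY is a preparation of 8 herbal granules, per the labels, and captopril inhibits angiotensin-converting enzyme and is used against hypertension. Each group had 3 arrays, and the drugs were given once daily by gavage for 16 weeks, with water for the WKY and SHR-C rats. The labels do not say whether each array held the RNA of 1 animal, so the p-values measure the spread between these samples. The number of arrays limits the precision of every value.

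Each array held 38321 probes that were not controls. Of these, 37277 carried an array design ID and no gene name in the sources used here, so the protein-coding and long non-coding transcripts that the study set out to profile could not be told apart. A further 962 probes covered both strands of 481 ultraconserved elements, genomic stretches that are nearly identical between distant mammals. A gene could be named for 39 probes of 38 genes, and 32 of those genes were bright enough to be tested. The share of probes well above background was 81.9% ± 7.19 on the WKY arrays, 64.6% ± 5.15 on SHR-C, 58.4% ± 6.29 on SHR-Bh and 62.0% ± 3.58 on SHR-Ca (SD, n = 3). All 3 WKY arrays, between 74.0% and 87.9%, lay above all 9 SHR arrays, which ran from 51.2% to 68.6%.

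The strains separated most in the data. The first principal component, with 69.5% of the variance of 29514 probes, parted the WKY arrays from the SHR arrays. Across probes, which are not independent replicates, Pearson's r was 0.768 to 0.833 between a WKY and an SHR array and 0.929 to 0.984 between arrays of different SHR groups. The second component, with 9.44% of the variance, did not follow treatment. SHR-Bh 2 (-86.6), SHR-Bh 3 (-88.3) and SHR-Ca 1 (-75.0) lay at its negative end, while SHR-Bh 1 (37.4), SHR-Ca 2 (49.6) and SHR-Ca 3 (51.4) lay on the positive side with the SHR-C arrays (8.84 to 81.9).

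**Figure D1:**
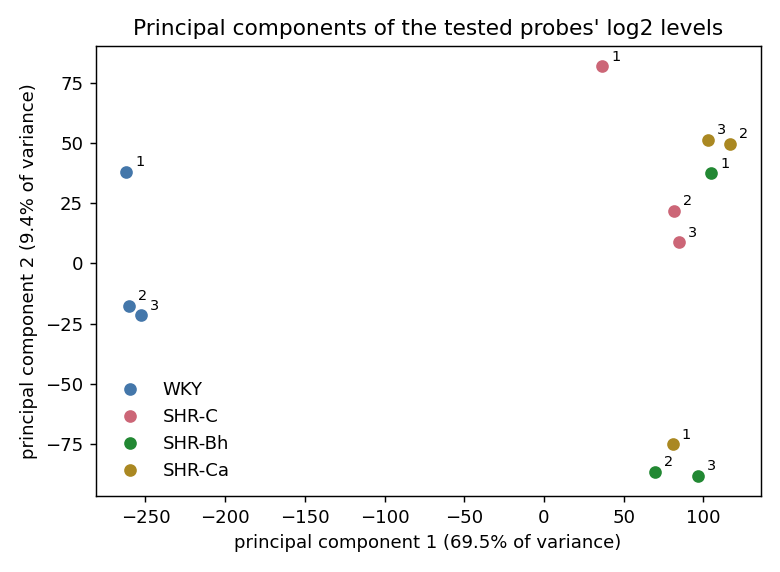
Scores of the 12 arrays on the first 2 principal components of the log2 levels of 29514 tested probes (arbitrary units), 1 point per array, coloured by group and numbered by replicate. WKY arrays lie at -253 or below on component 1, and SHR-Ca 1 lies beside SHR-Bh 2 and SHR-Bh 3 on component 2.

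The comparison of SHR-C with WKY asks how the aorta of untreated hypertensive rats differs from that of the normotensive strain. Cyp2e1, a cytochrome P450 enzyme that oxidises ethanol and other small molecules, showed the widest gap among the 32 named genes. Its level, as log2 intensity relative to the array's 75th percentile, was 5.01 ± 0.41 in SHR-C and -2.56 ± 0.16 in WKY (SD, n = 3), a rise of 7.57 (SE 0.29, limma adjusted p = 6.5e-08) or 189.7-fold. Cdh2, which encodes the cell adhesion protein N-cadherin, rose from -2.64 ± 0.17 to 0.81 ± 0.15, a change of 3.45 (SE 0.34, adjusted p = 9.8e-06). Eif4b, a translation initiation factor, rose 7.87-fold (2.98 on the log2 scale, SE 0.25, adjusted p = 3.8e-06), and Trim2, a ubiquitin ligase, rose 4.71-fold (2.24, SE 0.29, adjusted p = 5.6e-05). The rise of Cyp2e1 was 6.05 with normexp background correction and 8.33 with quantile normalization, and that of Cdh2 was 2.21 and 4.26.

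Ppp2r2b, a regulatory subunit of protein phosphatase 2A that is enriched in brain, was 1.56 ± 0.20 in SHR-C and -2.58 ± 0.36 in WKY (change 4.14, SE 1.38, adjusted p = 0.022). P2rx2, an ATP-gated cation channel, was -1.47 ± 0.37 in SHR-C against -4.82 ± 0.45 in WKY, where 2 of 3 arrays had it well above background (change 3.35, SE 1.27, adjusted p = 0.038). Ptk2b, a calcium-responsive tyrosine kinase, rose by 2.17 (SE 0.61, adjusted p = 0.009). With normexp and with quantile normalization the changes were 2.84 and 4.91 for Ppp2r2b, 1.37 and 4.47 for P2rx2, and 1.29 and 2.98 for Ptk2b. Ppp2r2b and P2rx2 varied widely within the treated groups, whose spread entered the same fit, and had large standard errors. The Ppp2r2b call was lost without WKY 1 (adjusted p = 0.059), WKY 2 (0.052) or SHR-C 2 (0.053), within a range of 2.8e-05 to 0.059 over all settings. The P2rx2 call was lost without any 1 of the 6 arrays (adjusted p between 0.062 and 0.098), with the scan session as a block (0.051) and with the replicate number as a block (0.063), within a range of 0.00011 to 0.098.

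Smaller rises were measured for Odf2l (1.93, SE 0.59, adjusted p = 0.014), for Enpp1, which makes pyrophosphate from extracellular ATP (1.38, SE 0.30, adjusted p = 0.0019), and for Ndfip1, an adaptor of Nedd4-family ubiquitin ligases (1.26, SE 0.23, adjusted p = 0.00073). Of the 32 named genes, 18 rose, none fell and 14 did not pass, and in 17 of the 18, which had been selected by the test, the groups did not overlap. Over all tested probes they did not overlap in 71.2%, where chance gives 10%. The others that rose by less, or with overlap, were Mex3c, Pdcd10, Ndfip2, Pld1, Nat1, Hprt1, Rpl13a and Hsp90ab1. The count of falls depended on the setting: 1 named gene fell with normexp, and 2 fell with array weights or with only these 2 groups in the fit. Both probes of Ldha, which encodes a lactate dehydrogenase subunit, were tested and differed in sign. The brighter one changed by -0.49 (SE 0.25, adjusted p = 0.11) and the other by 1.42 (SE 0.31, adjusted p = 0.0021).

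Genes commonly used as references had a custom set of probes with 30 spots each, grouped here after the names were seen. Of its 10 genes, Hprt1 (0.83), Rpl13a (0.72) and Hsp90ab1 (0.68) rose, and Actb, B2m, Gusb, Ldha, Pgk1, Rplp1 and Sdha did not pass. The median change of the 10 was -0.09, with a range of -0.49 to 0.83. Quantile normalization gave 2 rises and no fall with a median of -0.13, and normexp gave no rise and 1 fall with a median of -0.21.

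Over all 29618 tested probes, 18281 (61.7%) differed between SHR-C and WKY, 6489 higher and 11792 lower in SHR-C. At least 2-fold changes numbered 5177 higher and 10849 lower by fitted value, and 5159 and 10415 with the 3600 probes not well above background in the dimmer group taken at their bound. The standard error of a change had a median of 0.34. By fitted change, the top rises without a gene name were those of ASRNV20022264 (4.02 ± 0.15 against -5.87 ± 0.52, well above background on 1 of 3 WKY arrays, change 9.89, SE 2.95, adjusted p = 0.013) and ASRNV20024058 (change 9.16, SE 3.12, adjusted p = 0.024, also on 1 of 3 WKY arrays). The top falls by fitted change were those of ASRNV20004880, at least 183.2-fold lower and not well above background in SHR-C (adjusted p = 5.4e-07), and ASRNV20001199 (-2.57 ± 0.68 against 6.53 ± 0.16, change -9.09, adjusted p = 2.8e-07). With normexp the fitted changes of these 4 probes were 5.92, 6.05, -4.14 and -7.51, so the bound of ASRNV20004880 holds for the processed intensity alone. The ASRNV20024058 call was lost without WKY 1, WKY 2, SHR-C 2 or SHR-C 3, at adjusted p between 0.055 and 0.063, within a range of 1.8e-05 to 0.063 over all settings.

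The direction of the strain calls went with brightness, in part by construction. The probes were put in 5 equal groups by mean level over the 12 arrays. In the dimmest group 170 were higher and 4838 lower in SHR-C, and in the brightest 2192 were higher and 554 lower. As 9 of those arrays were SHR, a probe low in SHR fell into a dimmer group. The filter also let in probes well above background in WKY alone, which favours lower calls among dim probes. How much of the pattern this gives was not tested. Of all calls, 35.5% were higher with the 75th percentile scaling, 47.7% with quantile normalization (8325 of 17441) and 57.1% with normexp (6183 of 10830). The median change over all probes was -0.42, -0.09 and 0.18 under these 3 settings. No median change was subtracted from the changes above, so they are to be read beside those values. Among the 17797 probes well above background on all 12 arrays, 5499 were higher and 4055 lower. The 3 WKY arrays shared a scan session that held no SHR array, so strain and session cannot be told apart. With the session as a random block 17192 probes passed.

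**Figure D2:**
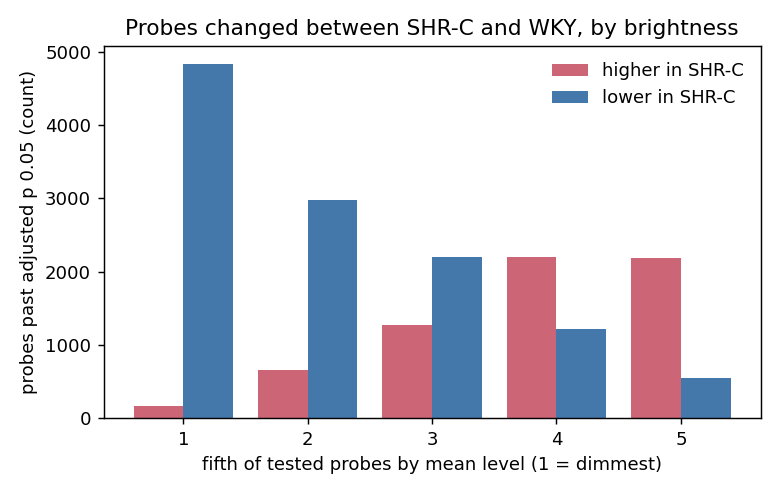
Number of probes past adjusted p 0.05 between SHR-C and WKY in each of 5 equal groups of the 29618 tested probes, ordered by mean log2 level over the 12 arrays. Bars give probes higher (red) and lower (blue) in SHR-C: there are 4838 lower calls in the dimmest group and 554 in the brightest, and 170 and 2192 higher calls.

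Ultraconserved elements, a group chosen after the probe names were seen, were mostly lower in SHR-C among the probes that passed the filter. Of their 466 tested probes, 49 were higher, 312 lower and 105 did not pass, with a median change of -1.99 against -0.40 for other probes, or -1.44 against -0.40 with probes not well above background in the dimmer group at their bound. Camera with a preset correlation gave adjusted p = 6e-08 over the 4 comparisons, and adjusted p = 0.37 with an estimated correlation. Random lists of other probes matched on brightness had a median of -1.63 (95% of lists between -1.79 and -1.47). The median turned to 0.07 with normexp, where the median over all tested probes was itself 0.18, and was -0.12 among probes well above background on all arrays. Both strands of an element were well above background on every array of the group for 122 of the 481 elements in WKY. The number was 34 in SHR-C, 20 in SHR-Bh and 33 in SHR-Ca. Of the 466 tested probes, 445 met the filter in WKY and 200 in SHR-C. The filter thus let in many probes for their signal in WKY, which favours lower calls and a negative median. With no filter the median was less negative, as given below.

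Strain differences were largely shared by treated and untreated SHRs. In all 3 SHR groups 16110 probes differed from WKY in the same direction, 5429 higher and 10681 lower, where independent lists of these sizes would share 372 and 2163. These comparisons share the WKY arrays, which lay in a scan session without SHR arrays. A common difference between those arrays and all SHR arrays would give such sharing. In 100 simulations of unchanged groups the highest count was 0, but these held no strain difference and so cannot weigh the sharing. With normexp 9133 probes were shared in this way, 4862 higher and 4271 lower, and with the strict filter on dim probes 8197, 4730 higher and 3467 lower. Cyp2e1 was 4.78 ± 0.46 in SHR-Bh and 6.17 ± 0.17 in SHR-Ca, both far above its WKY level of -2.56 ± 0.16.

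The comparison of SHR-Bh with SHR-C asks what the high dose of BSJY changed in hypertensive rats. None of the 32 named genes passed the test in limma, and 2 had an unadjusted p under 0.05. The 5 with the smallest p were P2rx2, Ptk2b, Ppp2r2b, Trim2 and Actb. P2rx2 was -4.81 ± 2.30 in SHR-Bh against -1.47 ± 0.37 in SHR-C (difference -3.34, SE 1.27, adjusted p = 0.40), with 1 of 3 SHR-Bh arrays well above background. Ptk2b differed by -1.54 (SE 0.61, adjusted p = 0.42) and Ppp2r2b by -2.93 (SE 1.38, adjusted p = 0.46). Trim2 differed by 0.59 (SE 0.29, adjusted p = 0.47) and Actb, cytoskeletal actin, by 0.77 (SE 0.39, adjusted p = 0.49). Leaving out 1 array of these groups put the Actb difference between 0.42 and 0.98. With normexp the difference was -0.80 for P2rx2, -0.80 for Ptk2b and -1.83 for Ppp2r2b. With the scan session as a block it was -5.91 for P2rx2, -2.55 for Ptk2b, -5.47 for Ppp2r2b and 1.03 for Actb, and that of Trim2 turned to -0.32, each with adjusted p = 1. These blocked values link the 2 groups through SHR-Ca arrays, since no session held both.

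The wide spread of Ppp2r2b, P2rx2 and Ptk2b in SHR-Bh came from differences between its arrays. Ppp2r2b was 1.42 on SHR-Bh 1, inside the range of the SHR-C arrays (1.33 to 1.69), and -2.73 and -2.79 on SHR-Bh 2 and SHR-Bh 3, inside the range of the WKY arrays (-2.93 to -2.21). P2rx2 was -2.24 on SHR-Bh 1 and not well above background on SHR-Bh 2 and SHR-Bh 3. Ptk2b was -1.01, -2.41 and -2.29 on SHR-Bh 1, 2 and 3. The same 3 genes parted the SHR-Ca arrays: Ppp2r2b was -3.22 on SHR-Ca 1, and 1.73 and 2.53 on SHR-Ca 2 and 3.

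**Figure D3:**
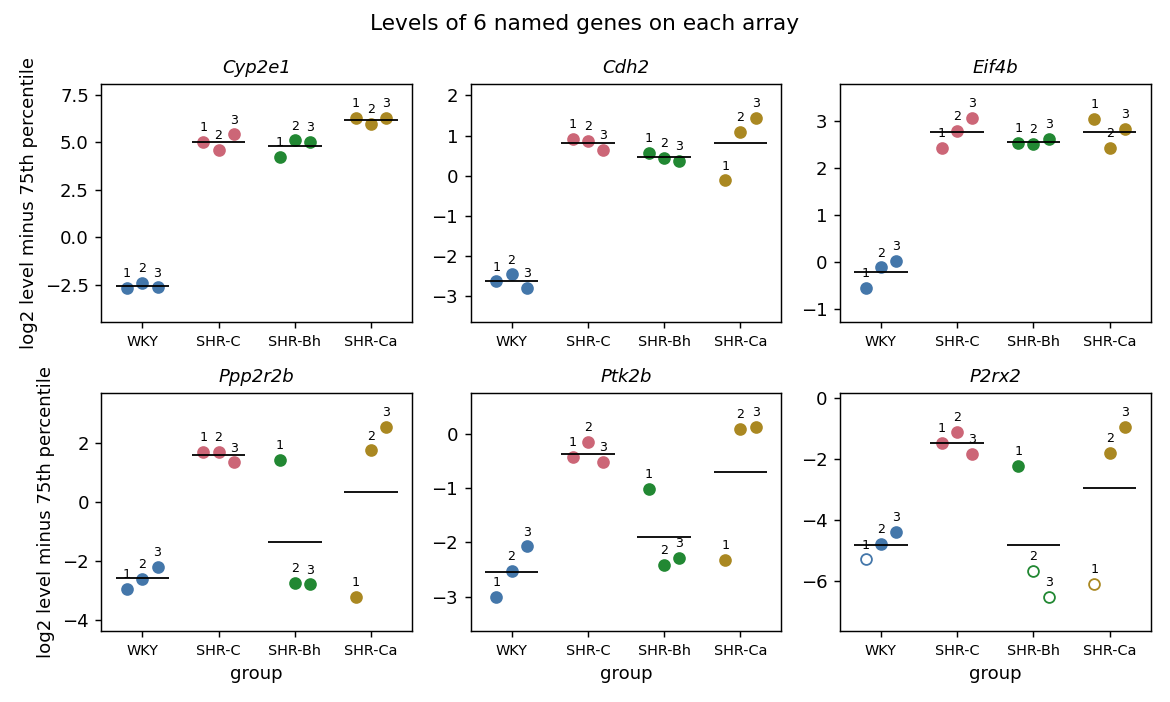
Log2 level, relative to the array's 75th percentile, of 6 named genes on each of the 12 arrays, numbered by replicate, with the group mean as a line and open points where the probe was not well above background. Cyp2e1, Cdh2 and Eif4b part all SHR arrays from WKY, whereas Ppp2r2b lies near its WKY level on SHR-Bh 2, SHR-Bh 3 and SHR-Ca 1 (-2.73, -2.79 and -3.22).

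Across all tested probes 28 fell in SHR-Bh against SHR-C and none rose in limma (3235 at an unadjusted p under 0.05). None has a gene name. The 22 that were well above background on at least 1 SHR-Bh array fell by 1.35 to 2.92 on the log2 scale, and the other 6 give bounds. ASRNV20028821, at least 2.90-fold lower (adjusted p = 0.039), and ASRNV20032723, at least 4.61-fold lower (adjusted p = 0.043), were first by fitted change and are among these 6. With normexp their fitted changes were -0.45 and -0.52 and their calls were lost (adjusted p = 0.99 for both). The count was 5 with normexp or with no filter, 190 with array weights, 18 with quantile normalization, and 0 with only these groups in the fit. It was 0 without any 1 of SHR-C 1, SHR-C 2, SHR-C 3, SHR-Bh 2 or SHR-Bh 3, and 92 (33 higher, 59 lower) without SHR-Bh 1. No scan session held both groups. With the session as a block among the SHR arrays no probe passed, and the median fitted change of the 28 went from -2.18 (median SE 0.27, or -2.09 with bounds) to -1.85 (median SE 0.62), so the call was lost mainly through the larger error.

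The comparison of SHR-Ca with SHR-C asks the same of captopril. None of the 32 named genes passed in limma, and 3 had an unadjusted p under 0.05. Cyp2e1 had the smallest p, at 6.17 ± 0.17 in SHR-Ca against 5.01 ± 0.41 in SHR-C (difference 1.16, SE 0.29, adjusted p = 0.17), and was higher on all 3 SHR-Ca arrays than on any SHR-C array. Actb differed by 1.30 (SE 0.39, adjusted p = 0.27). Pgk1 and Ldha, enzymes of glycolysis, differed by -0.70 (SE 0.28, adjusted p = 0.36) and -0.55 (SE 0.25, adjusted p = 0.41), and Sdha, a subunit of mitochondrial succinate dehydrogenase, by -1.01 (SE 0.48, adjusted p = 0.43). The Sdha difference was -0.42 without SHR-Ca 2 and -1.53 without SHR-Ca 1, and that of Pgk1 and Ldha was -0.46 and -0.34 without SHR-Ca 2. Within the session that held both groups, with 2 arrays of each, the difference was 1.11 for Cyp2e1, 1.36 for Actb, -0.77 for Pgk1, -0.49 for Ldha and -1.18 for Sdha (adjusted p = 0.95 for each). Over all settings the adjusted p of Cyp2e1 ran from 0.083 to 0.96.

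Across all tested probes 83 fell in SHR-Ca against SHR-C and none rose (3615 at an unadjusted p under 0.05). None has a gene name. The 48 that were well above background on at least 1 SHR-Ca array fell by 1.28 to 4.41 on the log2 scale, and the other 35 give bounds. They included ASRNV20030496, at -5.54 ± 1.70 against -1.13 ± 0.30 and well above background on 1 of 3 SHR-Ca arrays (change -4.41, SE 0.70, adjusted p = 0.028), and ASRNV20032257, at least 10.96-fold lower (adjusted p = 0.013). With normexp their fitted changes were -0.97 and -1.01 and their calls were lost (adjusted p = 0.95 for both). The count was 38 without SHR-C 1, 49 without SHR-C 2, 42 without SHR-Ca 2, 46 without SHR-Ca 3 and 149 without SHR-Ca 1. The ASRNV20032257 call was lost without SHR-C 1, SHR-C 2, SHR-Ca 2 or SHR-Ca 3 (adjusted p between 0.051 and 0.075), and that of ASRNV20030496 without these or SHR-C 3 (0.061 to 0.13). The count was 11 with normexp, 31 with the strict filter, 127 with array weights, and 0 with only these groups in the fit. With the session as a block, and on the 2 arrays of each group in the session that held both, no probe passed. The block draws its difference from those same arrays of that session, so the 2 settings give 1 estimate and not 2 checks. In it the median fitted change of the 83 went from -2.49 (median SE 0.36, or -2.09 with bounds) to -2.31 (median SE 0.44 with the block and 0.41 within the session). All 83 were lower there, on arrays that had helped select them.

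All but 1 of the 28 probes that fell with BSJY also fell with captopril, 27 in all. Both comparisons use the same SHR-C arrays, and in 100 simulations of unchanged groups the 28 and 83 probes with the smallest p shared a median of 3 in the same direction, with 27 reached in 1 of them. Over all probes the changes with the 2 treatments had r = 0.61 across probes, against a median of 0.51 in simulated unchanged groups (-0.79 to 0.93). The covariance was 0.26, against a median of 0.077 simulated (-0.14 to 0.44).

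Few probes were called as moved back towards WKY. On simulated arrays the fit recovered 4 of 100 probes changed 2-fold for BSJY and 3 of 100 for captopril, so moves of that size could go uncalled. Of the 28 and 83 that fell with treatment, 9 and 27 had risen in SHR-C against WKY, where independent lists would give 6.14 and 18.2, and 6 and 16 had fallen there as well. No named gene was among them. No probe that was lower in SHR-C than in WKY rose with either treatment in this fit, while 12 did with BSJY without SHR-Bh 1, 18 did with BSJY under array weights, and 6 did with captopril without SHR-Ca 1 or without SHR-C 2. Over all probes r between the strain difference and the treatment change was -0.03 for BSJY and 0.03 for captopril, inside the ranges of simulated unchanged groups (-0.96 to 0.60 with a median of -0.58, and -0.93 to 0.55 with a median of -0.46). The covariance was -0.034 and 0.037, also inside the simulated ranges (-0.51 to 0.071 and -0.53 to 0.14). The simulated groups held no strain difference, so lying inside their ranges cannot decide whether probes moved back towards WKY. With the session as a block, or with only the compared groups in the fit, both counts were 0. For BSJY the count was 35 without SHR-Bh 1 (23 that had risen in SHR-C and 12 that had fallen) and 0 without any 1 of the other 8 arrays. For captopril it was 17 without WKY 3, 12 without SHR-C 1, and 15 without SHR-Ca 2 or SHR-Ca 3.

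The direct comparison of SHR-Bh with SHR-Ca asks whether the 2 treatments differ. No probe passed in limma (smallest adjusted p = 0.066), while 2126 probes, with 4 named genes among 32, had an unadjusted p under 0.05. Among the named genes, Cyp2e1 had the smallest p, at 4.78 ± 0.46 in SHR-Bh against 6.17 ± 0.17 in SHR-Ca (difference -1.39, SE 0.29, adjusted p = 0.69), with no overlap between the arrays. Pgk1 differed by 0.81 (SE 0.28), Sdha by 1.28 (SE 0.48), Ldha by 0.57 (SE 0.25) and Fgf2, a fibroblast growth factor, by -1.08 (SE 0.49), each with adjusted p = 0.69. Within the session that held 2 SHR-Bh arrays and 1 SHR-Ca array the difference was -1.66 for Cyp2e1, 0.61 for Pgk1, 0.91 for Sdha, 0.48 for Ldha and -1.01 for Fgf2, too few arrays for a test to weigh. With the session as a block no probe passed. Without SHR-Ca 2 the difference was 0.69 for Sdha, 0.36 for Ldha and -0.60 for Fgf2, without SHR-Ca 1 it was -1.64 for Fgf2, and with normexp it was -0.25 for Fgf2. The count was 20 without SHR-Bh 1 and 1 without SHR-Ca 1. On simulated arrays the test recovered 51 of 100 probes changed 4-fold and none of 100 changed 2-fold in this comparison. Those arrays had 1 SD per probe for all groups and none that lay apart. The real median SD was 0.36 in SHR-Bh and 0.40 in SHR-Ca against 0.23 in WKY, so the real recovery may be lower.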

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

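The tests of the control probes, of bright probes without scaling, of scan session, dim signal and exchanged labels, and the counts of splits within single comparisons were chosen after the results they bear on had been seen. The test of quantile scaling, the count of bright probes with scaling, the list-based test and the splits for counts across comparisons were chosen before.

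Manufacturer's control probes, which enter no comparison, gave signal that differed between groups. Of 57 control types, corner spots left out, 8 were well above background on all 3 WKY arrays and on no SHR array, and none was on all 9 SHR arrays and no WKY array. Of the 57 types, 33 were lower and 23 higher in SHR-C than in WKY, many of them not well above background on any array. Among the 32 types well above background on at least 1 array, 25 were lower, with a median difference of -1.67. All 32 were well above background on WKY 3, so that choice of types itself favours lower values in SHR-C. The largest differences upwards were those of ETG10_13482, 2.83 higher in SHR-C on the log2 scale (-0.48 ± 1.80 against -3.31 ± 2.10, SD, n = 3, with overlap between the arrays), and (+)E1A_r60_a107, 1.21 higher, and neither was tested.

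The fall of dim probes in SHR-C against WKY, with 4838 lower and 170 higher calls in the dimmest of 5 groups by brightness, was set against scaling and unspecific hybridisation. Quantile scaling left 89.5% of the calls in that group lower, above the share set beforehand against the 75th percentile scaling as the cause. But the group was formed from the percentile-scaled means, mostly of SHR arrays, which builds lower calls into it. The share therefore cannot decide, and scaling stays open. More unspecific signal on the WKY arrays stays open: the median change over all 57 control types was -0.32 (SD 1.31), and many types were not well above background on any array. With normexp, whose offset shrinks the changes of dim probes, 393 probes of that group were lower and 174 higher. A strain difference in weakly expressed transcripts stays open and was not tested.

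For bright probes, those well above background on all 12 arrays, unspecific signal stays open as well. With scaling 4188 of them were at least 2-fold higher in SHR-C, which passed the bound of 2000 set beforehand against this explanation, but that bound was wrong by design, since signal added on WKY arrays also moves the percentile to which an array is scaled. In the test without scaling, chosen afterwards, 1224 were at least 2-fold higher and 5581 at least 2-fold lower, which decides for neither side. Scan session stays open too: 0 sessions held both strains, so strain and session cannot be told apart for these probes.

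SHR-Bh 1 and SHR-Ca 1 lay with arrays of another group. For SHR-Ca 1, scan session is argued against, since its r with SHR-Bh 2 and SHR-Bh 3, from other sessions, exceeded that with SHR-Ca 2, of its own session and treatment, by at least 0.0303 under 4 settings. Dim signal is argued against too: among probes well above background on all arrays, its lower r with those SHR-Bh arrays exceeded its higher r with an SHR-Ca array by 0.0106. For SHR-Bh 1 neither is settled, as its highest r, 0.984 with SHR-Ca 3, was within its session, its r with SHR-C 2 (0.980) and SHR-C 3 (0.979) of another session exceeded that with SHR-Bh 3 of its own (0.966) and with SHR-Ca 2 (0.964), and the same difference in bright probes was -0.0156. Exchanged labels and animals that differ within both treatments stay open and cannot be told apart, since 1 of the 2 arrays correlated better with both other arrays of the other treatment and 0 lists of cell type or response could be scored.

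In each comparison of 3 arrays with 3 there are 10 splits, too few for a share under 0.05. The real split gave 18281 calls for SHR-C against WKY (highest other 0), 28 for SHR-Bh against SHR-C (highest other 0) and 83 for SHR-Ca against SHR-C (highest other 1), and 1 split reached the real count in each. For SHR-C against WKY, the 3 other splits that part all 3 same-numbered pairs gave 0 as well. For SHR-Bh against SHR-Ca the real count was 0, which all 10 splits reach, and the highest other was 2151. That split exchanged SHR-Bh 1 and SHR-Ca 1 and points to a structure of the samples.

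For counts across comparisons, 100 splits were drawn. The 16110 probes shared by all 3 SHR groups were reached by 1 split, the real one (highest other 0). This argues against chance in how the arrays were grouped, and not against 1 common difference between WKY and all SHR arrays. A split that mixes the strains leaves few or no strain calls to share, so sharing beyond such a difference was not weighed. Probes changed back towards WKY were as many in 1 split for BSJY (real 9, highest other 0) and in 4 for captopril (real 27, highest other 16718). These shares decide nothing, since a split that mixes the strains leaves few or no strain calls to move back from: every other split of the WKY and SHR-C arrays alone gave 0. Independent lists would give 6.14 and 18.2 probes.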

How the results depend on the processing

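Leaving out both SHR-Bh 1 and SHR-Ca 1 and fitting within single sessions were chosen after seeing the data, and all other settings before. Signal over background limits the strain comparison: the dimmest of 5 groups of probes holds 4838 of the 11792 lower calls. Strain and scan session are confounded. The gene list tests could not be run under any setting, and the cause of a moved count was not tested unless its construction gives it.

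For SHR-C against WKY the count was 10830 with normexp and 9554 with the strict filter, which tests fewer probes, and between 16253 and 18094 without any 1 array. The count in all 3 SHR groups was 9133 and 8197 under the same settings, and 14445 to 16438 without any 1 array. In SHR-Bh against SHR-C, quantile normalization gave 18 (1 higher), normexp 5, no filter 5, array weights 190 (19 higher), only the compared groups 0 and the session block 0, and leaving out 1 array gave 0 to 92. In SHR-Ca against SHR-C, normexp gave 11, the strict filter 31 (1 higher), array weights 127 (4 higher), only the compared groups 0, the session block 0 and session 3 alone 0, and leaving out 1 array gave 38 to 149. The session block and session 3 alone rest on the same difference between the same arrays. SHR-Bh against SHR-Ca stayed at 0 under all settings with at least 2 arrays per group except 20 without SHR-Bh 1, 1 without SHR-Ca 1 (0 to 20 over all arrays left out) and the joint omission. Without both SHR-Bh 1 and SHR-Ca 1 the counts were 1052, 214 and 2494, and part of that follows from choosing arrays for lying apart. Then Ppp2r2b (-4.32, adjusted p = 8.2e-05, the lowest of a range up to 1), Ptk2b (-1.98) and P2rx2, not well above background on either SHR-Bh array left and so without a fold, passed in SHR-Bh against SHR-C, and Pgk1 (1.22), Sdha (2.11), Ldha (0.94) and Fgf2 (-1.95) in SHR-Bh against SHR-Ca.

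Probes changed back towards WKY with BSJY numbered 3 with normexp, 1 with no filter, 69 with array weights (51 that had risen in SHR-C and 18 that had fallen), 0 with only the compared groups, 0 with the session block, and 0 to 35 without 1 array. With captopril these were 8 with normexp, 12 with the strict filter, 0 with only the compared groups, 0 with the session block, 42 with the replicate block, and 12 to 40 without 1 array.

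Deviations of same-numbered arrays had r from -0.551 to 0.477, above 0.1 in 7 of 18 pairs. These were all 3 pairs of WKY with SHR-C, all 3 of WKY with SHR-Bh (0.307, 0.154 and 0.257) and 1 of SHR-C with SHR-Bh (0.122), so the numbers did not pair the samples in the 3 treatment comparisons. Of the 12 arrays, 2 correlated best with their own number. With the replicate block the counts were 17985, 22, 96 and 0 for the 4 comparisons, and 15880 and 13 for the probes shared by all SHR groups and those changed back with BSJY, and P2rx2 lost its call against WKY (adjusted p = 0.063, of a range of 0.00011 to 0.098). No other gene named for SHR-C against WKY lost its call with this block.

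Of the 10 genes named for SHR-C against WKY, 8 kept direction and call under every setting. P2rx2 also lost its call with the session block (adjusted p = 0.051). The median change of ultraconserved elements turned to 0.071 with normexp and was -1.16 with quantile normalization, -0.912 with no filter and -0.124 with the strict filter. Over all tested probes the median was itself 0.18 with normexp and -0.09 with quantile normalization.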

Other observations

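The test of exchanged labels and the genes Map2 and Dlg4 were chosen only after their values were seen, and the test by lists before. Map2 and Dlg4, a microtubule-associated protein and a postsynaptic scaffold of neurons, were set beside Ppp2r2b, P2rx2 and Ptk2b. Map2 was not well above background on SHR-Bh 2, SHR-Bh 3, SHR-Ca 1 and SHR-C 3, and lay at -3.47 on SHR-Bh 1, -3.84 on SHR-Ca 2 and -1.80 on SHR-Ca 3. On WKY 1, 2 and 3 it was -3.53, -3.72 and -3.78, well above background and near SHR-C 1 (-3.28) and SHR-C 2 (-3.50). There it did not follow Ppp2r2b, P2rx2 and Ptk2b, which were lower on every WKY array than on any SHR-C array. Dlg4, too dim to be tested, was well above background on SHR-C 1, SHR-C 2, SHR-Bh 1, SHR-Ca 2, SHR-Ca 3 and WKY 3. It was not on SHR-Bh 2, SHR-Bh 3, SHR-Ca 1, SHR-C 3, WKY 1 and WKY 2. On SHR-C 3 neither Map2 nor Dlg4 followed the other genes: Ppp2r2b (1.33), P2rx2 (-1.85) and Ptk2b (-0.53) were well above background there.

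A hypothesis is that the amount of nerve or other neuron-like tissue carried along with the aorta differed between animals of the same treatment, which could place SHR-Bh 1 and SHR-Ca 1 apart from their groups. The list of Schwann cell and neural markers fixed for this purpose had no member named on the array, and 0 lists reached 5 named genes, so for animals that differ within both treatments no test by markers was possible. An effect of treatment that reached 2 of 3 SHR-Bh arrays stays open as well, as does an exchange of labels, where 1 of the 2 arrays met the condition.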
